A study of Mus musculus with 59 samples.

How the data were processed

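Messenger RNA was sequenced from the prefrontal cortex of C57BL/6J mice in 59 libraries, prepared with a TruSeq Stranded mRNA kit per the labels' protocols. Mice were heterozygous for Ank2 (HT, 30 libraries) or wild type (WT, 29 libraries), female (30 libraries) or male (29 libraries), and had received vehicle, fluoxetine or lithium. Genotype, drug and sex from the labels made 12 groups of 5 libraries, except WT fluoxetine males with 4. Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 were used with build GRCm38. The notes give no settings. The deposited table holds signal, which here means estimated gene counts that the authors divided by a normalization factor, for 51456 Ensembl gene identifiers and 59 libraries. In each library the most frequent of the smallest values above 0, held by 29 to 72 genes, was taken as the step of 1 read. Between 28.8% and 66.7% of the low values of a library (median 57%) were whole multiples of this step, within a tolerance of 0.1 steps. Read counts could therefore not be recovered. Of the identifiers, 51285 matched GRCm38 gene models, which gave symbols, positions, transcript lengths and GC content.

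The values of a library summed to 30.3 to 33.8 M (median 32.3 M, with M for mega). Dividing each sum by the value taken as that of 1 read gave an estimated depth of 25.9 to 36.5 M reads (median 32.6 M), and 22566 to 23745 genes had a value above 0. Counting error is contained in the spread between libraries, from which all standard errors were taken. A further 0.0033% of the summed values belonged to identifiers without a gene model.

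Values were analysed as log2(value + 1) for the 16919 genes with a mean of at least 10 over all libraries. A single linear model with 12 group means was fitted with limma 3.58.1 in R 4.3.3 (limma-trend, robust empirical Bayes, 47 residual degrees of freedom), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Tests were two-sided. There were 22 comparisons: genotype in vehicle and each drug in each genotype, averaged over the sexes and in each sex; treated HT against WT vehicle; and the differences of these effects between genotypes or sexes. This was the branch planned for normalized values, and the branch for counts, with edgeR or a DESeq2 Wald test, was not run. Standard errors (SE) of log2 changes come from the model; means of groups are given with the standard deviation (SD) between libraries. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for annotation and plots.

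Gene lists were tested as wholes with limma's camera (preset correlation between genes of 0.01, adjusted over the lists within a comparison), with an estimated correlation and the rotation test fry beside it, for 7 comparisons averaged over the sexes. The 36 lists were excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes and myelin, immature oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells and pericytes, fibroblasts and meninges, choroid plexus, ependymal cells, blood cells, striatum, deep cortical layers, upper cortical layers, immediate early genes, circadian clock, glucocorticoid response, thyroid hormone response, cholesterol synthesis, inositol metabolism, Wnt and GSK3 signalling, serotonin signalling, neurotrophin and CREB targets, glutamate receptors and postsynaptic density, GABA receptors and inhibitory synapse, presynaptic release, ankyrins with spectrins and the axon initial segment, voltage-gated potassium and calcium channels, autism risk genes, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, unfolded protein and heat shock response, inflammation and interferon response, and perineuronal net and extracellular matrix. Some genes stand in more than 1 list.

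Besides Ank2, the genes named were the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 50 and the same sign in both sexes, up to 4 members with the smallest p of each called list, up to 5 genes with the smallest p of each drug by genotype comparison, and, where fewer than 5 genes were called, the 3 genes with the smallest p in each direction. Predicted genes were counted and not named. Groups, comparisons, lists, tests and the rule for naming genes were set before the data were examined. A gene named under another choice is said to be so.

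In each library, a length slope was computed as the slope of the log2 deviation from the gene mean on log2 transcript length, over genes with a mean of at least 250. Drug groups were compared with vehicle on this slope by exact permutation within each sex. Correlations of log2 changes across genes were given with the value that simulation without effects yields, and, for comparisons that share vehicle libraries, with the vehicle libraries divided so that none entered both. The sex of each library was checked with Xist and Ddx3y, and genotype with Ank2. The model was tested on simulated data in which 200 of 16919 genes were changed. At log2 changes of 0.25, 0.5 and 1 it recovered 41.8%, 74% and 93.3% of them in the genotype comparison averaged over the sexes, with 6.2% false among the calls. In females alone it recovered 23.9%, 65.7% and 87.3%, with 3.76% false. The simulated noise was normal and independent between genes, with the same SD in all groups, so these rates need not hold for the real libraries.

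Alternatives were quantile normalization, no filter on low values, pseudocounts of 0.5 and 10, a model of the compared groups alone, the replicate number as a block, and leaving out each library. After the data had been seen, 3 more were added: removal of a smooth trend on transcript length and GC content from each library (splines with 5 degrees of freedom each), scaling to equal sums, and leaving out 4 libraries that stood apart from their groups (HT vehicle female replicate 1, HT fluoxetine female replicates 2 and 4, and HT lithium male replicate 2). The labels give no litters, dams, library batches, drug doses or sequencing dates, and do not say which part of Ank2 was altered. Whether each library comes from a different animal is not stated either.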

Results

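RNA from the prefrontal cortex was measured at postnatal day 25 in mice with 1 altered copy of Ank2 (HT) and in wild-type mice (WT), after 3 weeks (days 3 to 24) of vehicle, fluoxetine or lithium through the mother's milk. Fluoxetine is a serotonin reuptake inhibitor and lithium a mood stabilizer that inhibits GSK3 and inositol monophosphatase. Each genotype and drug had 10 libraries, 5 per sex, except WT fluoxetine with 9. The estimated depth was 25.9 to 36.5 M reads per library. Xist, transcribed from the inactive X chromosome, was at 9791 or more in all 30 female libraries and at 71 or less in all 29 male libraries. The 9791 was that of HT fluoxetine female replicate 4, with 30734 to 40609 in the other 4 libraries of its group. The Y-linked gene Ddx3y was at 669 or more in males and at 6 or less in females.

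Ank2 codes for ankyrin-B, an adaptor between membrane proteins and the spectrin cytoskeleton (ENSMUSG00000032826, chromosome 3, 126921612 to 127499350, GRCm38). Its normalized value was 28470 ± 2080 (SD, n = 10) in WT vehicle and 19580 ± 660 (SD, n = 10) in HT vehicle libraries. All 30 HT libraries, at 22813 or less, were below every WT vehicle library, the lowest of which was at 23284. The normalized value was 32530 ± 1880 (SD, n = 9) in WT fluoxetine and 21590 ± 1680 (SD, n = 10) in HT fluoxetine libraries. It was 27510 ± 1080 (SD, n = 10) in WT lithium and 20080 ± 1440 (SD, n = 10) in HT lithium libraries.

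**Figure D1:**
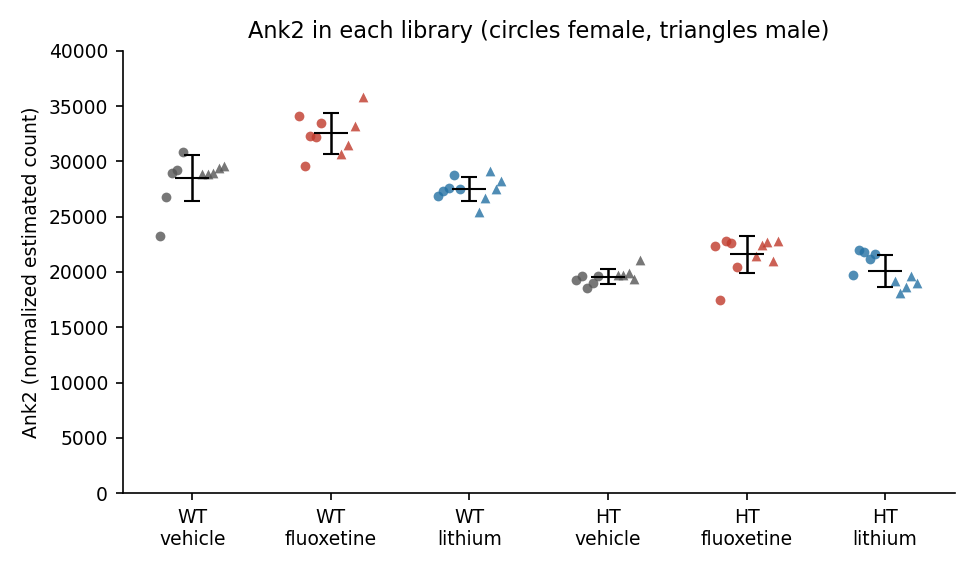
Normalized value of Ank2 in each of 59 libraries (circles female, triangles male), by genotype and drug, with the mean and SD of each group. The HT libraries lie at 22813 or less and the WT vehicle libraries at 23284 or more.

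The first comparison asks what the altered Ank2 copy changes in untreated cortex. Ank2 fell to 0.689-fold in HT vehicle libraries (log2 change -0.54, SE 0.04, n = 10 per genotype, adjusted p = 5e-15), by 0.53 on the log2 scale in females and by 0.55 in males. Its mean in females was 19220 in HT (SD 470) and 27810 in WT (SD 2920), and a model of the compared groups alone called no gene in females. No other gene passed: the limma test called 1 of 16919 genes, with 578 at an unadjusted p under 0.05. The genes with the next smallest p were Nf1, a negative regulator of Ras (0.14, SE 0.04), Top3a, a DNA topoisomerase (0.27, SE 0.08), and Tmem229a (0.13, SE 0.04) upward, and Armh4 (-0.18, SE 0.05), the exocyst gene Exoc7 (-0.14, SE 0.04) and Adck1 (-0.11, SE 0.03) downward, with adjusted p = 0.98 for Armh4 and 1 for the others. Without HT vehicle female replicate 2, HT vehicle male replicate 2 or WT vehicle female replicate 5 the count was 2. With no filter on low values it was 4.

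Among the gene lists, camera called 8 in the genotype comparison, although Ank2 was the sole list member to pass over all genes or adjusted over the list alone. Markers of striatum had a mean log2 change of 0.22 (SE 0.19, 20 of 20 higher, adjusted p = 6.6e-05). Their level was high in HT vehicle male replicates 1, 2 and 4 (deviations 0.519, 1.43 and 0.731), while the 5 HT vehicle females lay at -0.293 to -0.118, and without male replicate 2 the list was not called. Among these markers were Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32 (0.28), and Pde10a, a striatal phosphodiesterase (0.23). Oligodendrocyte and myelin genes had a mean of 0.10 (28 of 33 higher, adjusted p = 0.00082), with the myelin regulator Myrf at 0.19, and immature oligodendrocyte genes 0.10 (12 of 14 higher, adjusted p = 0.0038), with Gpr17 at 0.14. Microglia genes had a mean of 0.04 (21 of 27 higher, adjusted p = 0.0018), with P2ry12 at 0.16, and genes of endothelial cells and pericytes 0.04 (20 of 24 higher, adjusted p = 0.0076), with the VEGF receptor Kdr at 0.20. Blood cell genes had a mean of 0.24 (7 of 8 higher, adjusted p = 0.0009), with the haemoglobin gene Hba-a2 at 0.36, and mitochondrially encoded mRNAs 0.08 (11 of 13 higher, adjusted p = 0.0031). Nuclear-encoded oxidative phosphorylation genes had a mean of -0.03 (20 of 80 higher, adjusted p = 6.6e-05), with the complex III gene Uqcrc2 at -0.10. None of the 8 lists was called with an estimated correlation, where adjusted p = 0.99 for oligodendrocytes and myelin and 0.94 for the other 7, or by fry. Without WT vehicle male replicate 1 the number of called lists was 4. The list of ankyrins, spectrins and the axon initial segment, which holds Ank2, had a mean of -0.01 (adjusted p = 0.66), and autism risk genes had a mean of 0.00 (adjusted p = 0.99).

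The second comparison asks what fluoxetine does in WT cortex. In fluoxetine libraries, mRNAs of the cytoplasmic ribosome and of the mitochondrial respiratory chain were lower, and those of synaptic, ion channel and axonal proteins higher. Camera called the presynaptic, channel and axonal lists with the preset correlation and not with an estimated one. Fry called 13 lists in this comparison, against 12 by camera with the preset correlation. No batch is given in the labels, and the libraries also differ in a length slope. The differences between fluoxetine and vehicle libraries are therefore not shown to come from the drug. In all, limma called 1184 genes higher and 1316 lower (2500 together, n = 9 fluoxetine and 10 vehicle libraries), with a median size of 0.20 on the log2 scale and 22 genes changed over 2-fold. Of 78 ribosomal protein genes, 60 fell (67 adjusted over the list alone; mean -0.26, SE 0.04, adjusted p = 3.2e-48), such as Rpl26 to 0.755-fold (adjusted p = 6.8e-10) and Rps18 to 0.751-fold. Of 80 nuclear genes of oxidative phosphorylation, 61 fell (66 over the list alone; mean -0.21, adjusted p = 6.2e-45), such as the ATP synthase genes Atp5j2 to 0.735-fold and Atp5e to 0.693-fold. Both lists stayed called with an estimated correlation, at adjusted p = 0.015 and 0.0071.

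Of 87 autism risk genes, 38 rose and 2 fell in WT fluoxetine libraries (46 and 2 adjusted over the list alone; mean 0.12, adjusted p = 1.6e-15), such as the ubiquitin ligase gene Ube3a (1.22-fold) and the kinase gene Taok1 (1.25-fold). Of 61 genes of glutamate receptors and the postsynaptic density, 15 rose (19 over the list alone; mean 0.11, adjusted p = 4.5e-09), among them the NMDA receptor subunits Grin2b (1.3-fold) and Grin2a (1.31-fold). Of 29 genes of GABA receptors and the inhibitory synapse, 7 rose (9 over the list alone; mean 0.08, adjusted p = 0.00032), and of 32 genes of inositol metabolism 6 rose (7 over the list alone; mean 0.11, adjusted p = 0.0037), among them the inositol trisphosphate receptor Itpr1 (1.21-fold). With an estimated correlation these 4 lists stayed called, at adjusted p = 0.0057, 0.032, 0.025 and 0.012. Of 40 genes of ankyrins, spectrins and the axon initial segment, 15 rose (22 over the list alone; mean 0.13, adjusted p = 6.1e-09, adjusted p = 0.062 with an estimated correlation), with Ank3, which codes for ankyrin-G, at 1.24-fold. Of 57 potassium and calcium channel genes, 17 rose (20 over the list alone; mean 0.10, adjusted p = 4.7e-06, adjusted p = 0.062 with an estimated correlation). Of 54 presynaptic genes, 17 rose and 1 fell (19 and 1 over the list alone; mean 0.10, adjusted p = 1.1e-06, adjusted p = 0.31 with an estimated correlation), with the vesicle gene Syn1 0.25 higher on the log2 scale. Of 43 Wnt and GSK3 genes, 4 rose and 1 fell (the same numbers over the list alone; mean 0.05, adjusted p = 0.043, adjusted p = 0.31 with an estimated correlation), with the kinase gene Gsk3b at 1.2-fold. Ank2 rose to 1.14-fold (log2 change 0.20, adjusted p = 0.00035).

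Genes of cholesterol synthesis were lower with fluoxetine in WT cortex: 16 of 26 fell (17 fell and 1 rose adjusted over the list alone; mean -0.16, SE 0.04, adjusted p = 4.5e-09, adjusted p = 0.12 with an estimated correlation). Fdps, the farnesyl diphosphate synthase, fell to 0.783-fold and Idi1, the isopentenyl diphosphate isomerase, to 0.815-fold. Of 8 blood cell genes, 5 fell (6 over the list alone; mean -0.42, SE 0.13, adjusted p = 0.00011, adjusted p = 0.12 with an estimated correlation), with the beta globin Hbb-bt at 0.564-fold. The genes with the largest rises included Bc1, a noncoding RNA of dendrites (2.01-fold), Brca2, a DNA repair gene (1.81-fold), Syt2, a synaptic vesicle calcium sensor (1.57-fold), Aff2 (1.41-fold) and the mitochondrial mt-Nd4l (1.39-fold). Those with the largest falls included Lars2, the mitochondrial leucyl-tRNA synthetase (0.641-fold), Dnaaf2 (0.652-fold), Rpl24 (0.677-fold) and the splicing gene Snrpg (0.687-fold). After the trend with transcript length and GC content was removed, 850 genes were called, 668 of them among the 2500. Ribosomal, oxidative phosphorylation and cholesterol lists stayed called (adjusted p = 1.1e-23, 1.1e-16 and 2.2e-11), as did Grin2b, Ank3 and Taok1. Inositol metabolism (adjusted p = 0.073), GABA receptors (adjusted p = 0.23), Ank2 (log2 change 0.06, adjusted p = 0.5), Ube3a, Itpr1 and Brca2 did not.

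**Figure D2:**
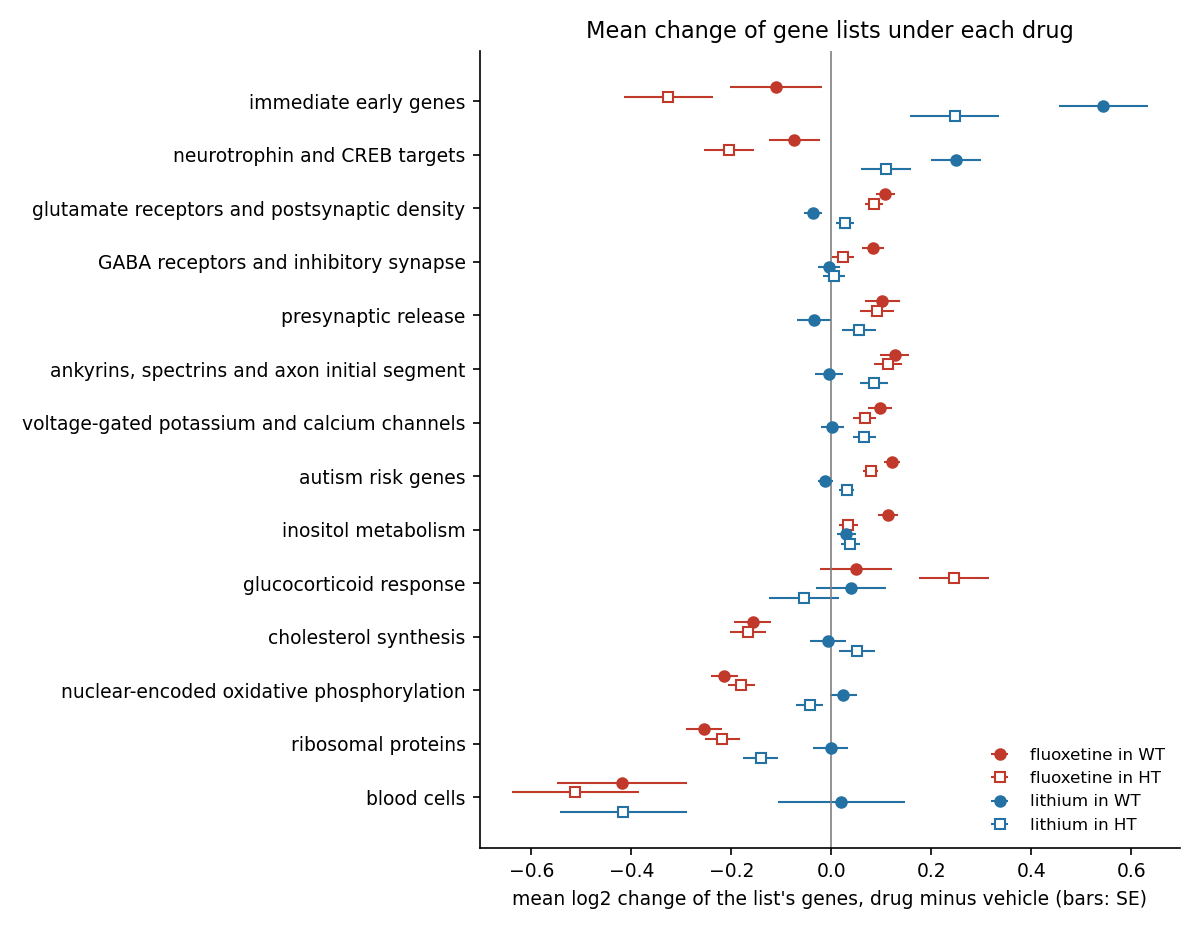
Mean log2 change of the genes of 14 lists, drug minus vehicle, with bars for the SE, for fluoxetine (red) and lithium (blue) in WT (filled) and HT (open). Ribosomal protein genes averaged -0.26 with fluoxetine in WT and -0.22 in HT, and immediate early genes averaged 0.54 with lithium in WT and 0.25 in HT.

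In HT cortex, fluoxetine gave 1122 genes higher and 1248 lower (2370 together, n = 10 per group), with a median size of 0.20 and 25 genes over 2-fold. Camera called 21 lists with the preset correlation, and fry called 17. Of 78 ribosomal protein genes, 54 fell (59 adjusted over the list alone; mean -0.22, SE 0.04, adjusted p = 7.9e-38), such as Rpl34 to 0.754-fold, and of 80 oxidative phosphorylation genes 57 fell (58 fell and 1 rose over the list alone; mean -0.18, adjusted p = 4.9e-33), such as the cytochrome oxidase gene Cox7a2 to 0.719-fold. Of 87 autism risk genes, 22 rose (28 over the list alone; mean 0.08, adjusted p = 6.5e-09), such as Tbl1xr1 (1.22-fold), and of 32 inositol genes 3 rose (3 over the list alone; adjusted p = 0.011), among them Cdipt (1.11-fold). With an estimated correlation each of these 4 lists had adjusted p = 0.044. Genes that rose were 19 of 61 for glutamate receptors (21 over the list alone; adjusted p = 6.3e-08, adjusted p = 0.068 with an estimated correlation), with the scaffold gene Shank1 at 1.28-fold, and 11 of 40 for ankyrins and spectrins (13 over the list alone; adjusted p = 5.2e-09, adjusted p = 0.075 with an estimated correlation), with Ank3 0.25 higher on the log2 scale. They were 16 of 54 for presynaptic release (20 over the list alone; adjusted p = 3.7e-07, adjusted p = 0.25 with an estimated correlation), with the dynamin gene Dnm1 at 1.21-fold, 16 of 57 for channels (16 over the list alone; adjusted p = 0.00014, adjusted p = 0.13 with an estimated correlation), and 4 of 29 for GABA receptors (4 over the list alone; adjusted p = 0.04, adjusted p = 0.24 with an estimated correlation), with the GABA receptor auxiliary gene Shisa7 0.25 higher. Ank2 rose to 1.1-fold (log2 change 0.14, adjusted p = 0.01). After length and GC correction 1534 genes were called, 1289 of them among the 2370, without Ank2 (log2 change 0.05, adjusted p = 0.5), GABA receptors (adjusted p = 0.54) or inositol metabolism (adjusted p = 0.1).

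Cholesterol synthesis fell in HT fluoxetine libraries as well, in 13 of 26 genes (16 over the list alone; mean -0.17, SE 0.04, adjusted p = 5.2e-09, adjusted p = 0.13 with an estimated correlation), among them Stard4 (0.764-fold) and Insig1 (0.82-fold). Genes induced by glucocorticoids had 9 rises and 1 fall among 25 (12 and 1 over the list alone; mean 0.25, SE 0.07, adjusted p = 0.00025, adjusted p = 0.25 with an estimated correlation), led by the lipid droplet gene Plin4 (3.7-fold, adjusted p = 1.7e-06), Arrdc2 (1.45-fold) and the kinase gene Sgk1 (1.34-fold). Immediate early genes, which neurons transcribe on activity, had 15 falls among 42 (18 over the list alone; mean -0.33, SE 0.09, adjusted p = 3e-07, adjusted p = 0.25 with an estimated correlation), with Egr2 at 0.36-fold, Fos at 0.413-fold, Arc at 0.498-fold and Npas4 at 0.546-fold. HT vehicle female replicate 1 held the highest HT vehicle values of Fos (1556) and Arc (8341), and without it the list averaged -0.34 (SE 0.12) in females and -0.19 (SE 0.12) in males. Inflammation and interferon genes fell in 10 of 28 cases (12 over the list alone; mean -0.25, adjusted p = 6.2e-06, adjusted p = 0.09 with an estimated correlation), among them Ifitm3 (0.737-fold) and the MHC gene H2-D1 (0.844-fold). Blood cell genes fell in 5 of 8 cases (6 over the list alone; adjusted p = 1e-05, adjusted p = 0.088 with an estimated correlation). Mitochondrially encoded mRNAs rose in 5 of 13 cases (5 over the list alone; adjusted p = 0.0082, adjusted p = 0.42 with an estimated correlation), with mt-Nd4l at 1.7-fold.

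Cell type lists called in HT fluoxetine libraries were lost with an estimated correlation. Oligodendrocyte precursor genes rose in 4 of 19 cases (5 over the list alone; adjusted p = 0.0059, adjusted p = 0.21 with an estimated correlation), with the receptor gene Pdgfra at 1.21-fold, and astrocyte genes had 6 rises and 4 falls among 24 (the same numbers over the list alone; adjusted p = 0.046, adjusted p = 0.62 with an estimated correlation), with the glutamate transporter Slc1a2 at 1.22-fold. Inhibitory neuron genes fell in 3 of 26 cases (3 over the list alone; adjusted p = 0.012, adjusted p = 0.26 with an estimated correlation), with the neuropeptide gene Cort at 0.746-fold. Without HT vehicle female replicate 1, their mean was -0.36 (SE 0.11) in females and -0.06 (SE 0.10) in males. Mean deviations of 6 olfactory bulb markers (S100a5, Doc2g, Th, Trh, Shisa3 and Vipr2) were 1.5, 1.24, 2.1, 1.81 and 0.09 in the HT vehicle females. They were -0.78, -3.68, -0.18, -2.05 and 0.88 in the HT fluoxetine females. Oligodendrocyte and myelin genes had 1 rise among 33 (0 over the list alone; adjusted p = 0.0017, adjusted p = 0.64 with an estimated correlation), choroid plexus 1 rise among 15 (1 over the list alone; adjusted p = 0.029, adjusted p = 0.62 with an estimated correlation), and striatum 1 fall among 20 (0 over the list alone; adjusted p = 0.037, adjusted p = 0.67 with an estimated correlation). HT fluoxetine female replicate 2 had a choroid plexus level 5.34 log2 units above the gene means, against -0.326 to 0.305 in the other 4 libraries of its group, and an oligodendrocyte and myelin level of 1.34. Of genes known from the dentate gyrus and singled out after their values were seen, Prox1 was at 4900, C1ql2 at 1150 and Dsp at 1363 in this library, against 404 to 438, 1 to 11 and 6 to 31 in the other 4. Without the 4 libraries that stood apart from their groups, limma called 2733 genes in HT, and the oligodendrocyte and myelin list changed sign and was not called (adjusted p = 0.97).

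The effects of fluoxetine in WT and HT shared 464 genes higher in both genotypes (78.5 expected if independent) and 697 lower in both (97.1 expected), and none that went opposite ways. No gene differed in its response between genotypes or sexes by limma (0 called each, with 1291 and 2146 at an unadjusted p under 0.05). The smallest p for a difference between genotypes were those of Pnpla7 (0.61), Cd93 (-0.49), Ube3a (-0.26), Nf1 (-0.24) and Ddx6 (-0.19), each with adjusted p = 0.26. In WT, 1448 genes passed in females and 896 in males. The female count was 946 without WT fluoxetine replicate 1, 916 without replicate 5 and 674 without WT vehicle replicate 1. The male count was 285 without WT fluoxetine replicate 1, 562 without WT vehicle replicate 3 and 473 without replicate 4. The female count was 707 with a model of the compared groups alone and 326 after length and GC correction, and the male count 102 and 120. In HT, 1480 genes passed in females and 569 in males, and a model of the compared groups alone called 1 in females and 618 in males. For fluoxetine in HT, females, the count was 891 after length and GC correction, 958 without a filter on low values and 889 without the 4 libraries that stood apart. For fluoxetine in HT, males, it was 196 after the correction and 877 without the 4 libraries. The female count was 802 without HT fluoxetine replicate 2 and 986, 792 and 708 without HT vehicle replicates 2, 3 and 4. The male count was 351 without HT vehicle replicate 4.

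Fluoxetine libraries differed from vehicle libraries in how values varied with transcript length. The length slope averaged 0.054 (SD 0.024, n = 9) in WT fluoxetine against -0.033 (SD 0.014, n = 10) in WT vehicle libraries (exact permutation p = 3.1e-05, adjusted over 4 tests 0.00012). It averaged 0.033 (SD 0.021, n = 10) in HT fluoxetine against -0.023 (SD 0.036, n = 10) in HT vehicle libraries (exact permutation p = 0.00072, adjusted 0.0014). In lithium the difference was 0.007 in WT (exact permutation p = 0.29) and 0.024 in HT (exact permutation p = 0.1, adjusted 0.13). The 25 highest slopes were those of all 19 fluoxetine libraries, all 5 HT lithium female libraries and HT vehicle female replicate 1, from -0.007 upward, while the other 34 libraries lay at -0.009 or lower. Slopes ran from 0.000 to 0.060 in HT lithium females and from -0.067 to -0.020 in HT lithium males.

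**Figure D3:**
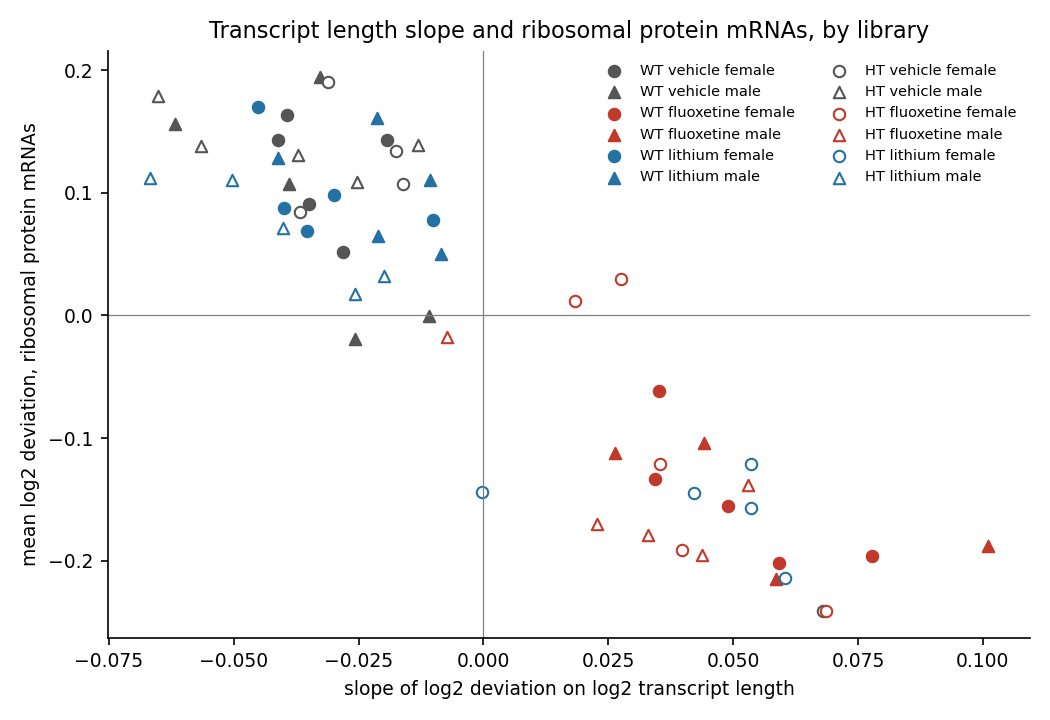
Slope of log2 deviation on log2 transcript length (horizontal) against the mean log2 deviation of ribosomal protein mRNAs (vertical), 1 point per library, coloured by drug, with open symbols for HT. The 19 fluoxetine libraries, the 5 HT lithium female libraries and HT vehicle female replicate 1 lie at slopes of -0.007 or higher, and the other 34 libraries at -0.009 or lower.

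Means of ribosomal, respiratory and neuronal lists lay apart between the sexes in HT lithium libraries, whose slopes lie apart as well. Leaving out HT vehicle female replicate 1, ribosomal protein genes averaged -0.29 (SE 0.04) in HT lithium females and -0.07 (SE 0.04) in HT lithium males against vehicle, and oxidative phosphorylation genes -0.16 (SE 0.03) and 0.02 (SE 0.03). Autism risk genes averaged 0.10 (SE 0.02) in HT lithium females and -0.01 (SE 0.02) in males, glutamate receptor genes 0.09 (SE 0.03) and -0.01 (SE 0.02), and genes of ankyrins and spectrins 0.17 (SE 0.04) and 0.03 (SE 0.04). Set against HT lithium females, which have similar slopes, HT fluoxetine females differed by 0.05 (SE 0.04) in ribosomal, -0.05 (SE 0.03) in oxidative phosphorylation and -0.01 (SE 0.02) in autism risk genes. In males the differences were -0.21 (SE 0.04), -0.23 (SE 0.03) and 0.11 (SE 0.02). Cholesterol synthesis genes had means of -0.22 (SE 0.05) in HT females and -0.21 (SE 0.05) in HT males for fluoxetine minus lithium, and glucocorticoid response genes of 0.32 (SE 0.10) and 0.28 (SE 0.10). Lists were tested neither for fluoxetine against lithium nor for differences between sexes. The pseudogene Eif4a-ps4, singled out after its values were seen, was at 152 to 949 in HT lithium females and 0 in HT lithium males. It was at 632 in HT vehicle female replicate 1 and at 273 to 965 in most fluoxetine libraries. HT fluoxetine female replicate 4, HT fluoxetine male replicate 4 and WT fluoxetine male replicate 4 were at 0. The libraries with lower slopes lay at 0 to 356, most of them at 0. No library batch is given in the labels, so a batch and fluoxetine cannot be separated.

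The third comparison asks what lithium does in WT cortex. Genes that neurons transcribe on activity were higher in lithium libraries. The labels give no batch or litter, so differences between lithium and vehicle libraries are not shown to come from the drug. Of 42 immediate early genes, 27 rose (34 adjusted over the list alone) and all 42 had higher means (mean 0.54, SE 0.09, adjusted p = 8.9e-44, adjusted p = 0.0019 with an estimated correlation). Arc, whose protein acts at synapses, rose from 2330 ± 937 to 6820 ± 1820 (SD, n = 10 each; 3.02-fold, adjusted p = 0.0013). The transcription factor genes Egr2 (2.69-fold), Fos (2.1-fold), Nr4a1 (2.01-fold), Junb (1.85-fold) and Fosb (1.8-fold) rose too, as did the phosphatase genes Dusp1 (2.07-fold) and Dusp6 (1.51-fold), and Gadd45b (1.59-fold, adjusted p = 2.9e-05). Of 27 neurotrophin and CREB target genes, 7 rose (7 over the list alone; mean 0.25, adjusted p = 2.8e-07, adjusted p = 0.016 with an estimated correlation), among them the secreted neuropeptide precursor Vgf (1.37-fold).

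Of 34 unfolded protein and heat shock genes, 3 rose with lithium in WT (3 over the list alone; mean 0.08, adjusted p = 0.013, adjusted p = 1 with an estimated correlation): the stress response genes Atf4 (log2 change 0.25), Sesn2 (1.25-fold) and Atf3 (2.07-fold). Of 61 glutamate receptor genes none passed, over all genes or over the list alone (mean -0.04, adjusted p = 0.013, adjusted p = 1 with an estimated correlation). In all, limma called 225 genes higher and 151 lower (376 together, n = 10 per group), with a median size of 0.25 and 10 genes over 2-fold. Other large rises were those of the death receptor gene Tnfrsf25 (1.82-fold), Csrnp1 (1.78-fold) and the matricellular gene Ccn1 (1.89-fold). Pnck, a kinase gene on the X chromosome, fell to 0.743-fold (adjusted p = 1.6e-06), and Frat1, which codes for a GSK3-binding protein, to 0.685-fold. Further falls were those of Gkn3 (0.655-fold), Zfp867 (0.688-fold), Fdxacb1 (0.74-fold), Parp16 (0.765-fold), and of Tfap4 (0.698-fold), Cd180 (0.753-fold) and Ovca2 (0.778-fold). Without a filter on low values 212 genes were called, without Tfap4, Cd180 and Ovca2. Ank2 had a log2 change of -0.05 (adjusted p = 0.66). The count was 248 without WT lithium female replicate 1, 226 without female replicate 3, 214 without male replicate 4, 231 without WT vehicle male replicate 3, and 582 without the 4 libraries of other groups that stood apart. The number of called lists was 7 without WT lithium male replicate 3 or WT vehicle male replicate 3 or 4.

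**Figure D4:**
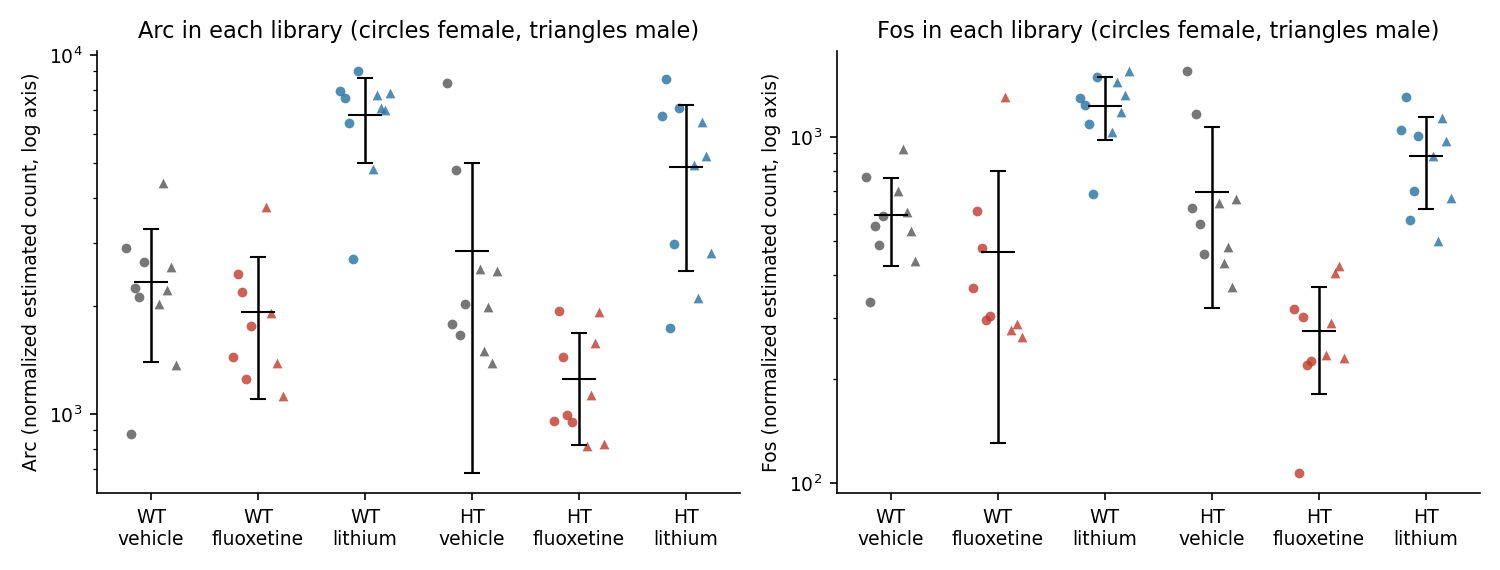
Normalized values of Arc and Fos on log axes in each library (circles female, triangles male), by genotype and drug, with the mean and SD of each group. In WT the mean of Arc was 2330 with vehicle and 6820 with lithium.

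In HT cortex, lithium gave 465 genes higher and 382 lower (847 together, n = 10 per group), with a median size of 0.21 and 12 genes over 2-fold. Of 42 immediate early genes 7 rose (19 over the list alone; mean 0.25, SE 0.09, adjusted p = 8.7e-11, adjusted p = 0.25 with an estimated correlation), among them Ier5 (1.45-fold), Dusp6 (1.39-fold) and the neurotrophin gene Bdnf (1.36-fold). Leaving out HT vehicle female replicate 1, which had the highest vehicle value of Arc, this list averaged 0.35 (SE 0.12) in females and 0.27 (SE 0.12) in males. Of 27 neurotrophin and CREB targets 4 rose (5 over the list alone; adjusted p = 0.0093, adjusted p = 0.34 with an estimated correlation), with Vgf at 1.35-fold. Of 23 circadian clock genes 4 rose (4 rose and 1 fell over the list alone; adjusted p = 0.028, adjusted p = 0.51 with an estimated correlation), among them Per1 (1.3-fold) and Nr1d1 (1.25-fold). Of 32 inositol genes 2 rose (5 over the list alone; adjusted p = 0.023, adjusted p = 0.2 with an estimated correlation): Slc5a3, the sodium and myo-inositol cotransporter (1.27-fold), and Cdipt, the phosphatidylinositol synthase (1.13-fold). Without HT vehicle female replicate 1, the inositol list averaged 0.08 (SE 0.03) in females and 0.01 (SE 0.03) in males. Of 34 unfolded protein and heat shock genes 3 rose (10 over the list alone; adjusted p = 3.6e-05, adjusted p = 0.5 with an estimated correlation), with the chaperone gene Hsph1 at 1.17-fold.

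Blood cell genes fell with lithium in HT in 2 of 8 cases (7 over the list alone; mean -0.42, adjusted p = 2.3e-05, adjusted p = 0.2 with an estimated correlation). Microglia genes fell in 2 of 27 cases (4 over the list alone; adjusted p = 0.00048, adjusted p = 0.52 with an estimated correlation), with P2ry13 at 0.815-fold, inflammation genes in 1 of 28 (4 over the list alone; adjusted p = 0.00033, adjusted p = 0.27 with an estimated correlation), and immature oligodendrocyte genes in 1 of 14 (6 over the list alone; adjusted p = 0.0013, adjusted p = 0.51 with an estimated correlation). Cholesterol synthesis had 1 rise among 26 (1 over the list alone; mean 0.05, adjusted p = 0.035, adjusted p = 0.64 with an estimated correlation), Hsd17b7 at 1.17-fold. Among the largest changes, Tnfrsf25 rose again (1.81-fold), as did Klf10 (1.55-fold) and Syt2 (1.5-fold), and Ltbp2 (0.489-fold), Angptl4 (0.571-fold), Cd1d1 (0.578-fold), Mkrn3 (0.627-fold) and Cd180 (0.685-fold) fell.

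The other lists called with lithium in HT had means farther from 0 in females, whose libraries have the higher length slopes, than in males. The same held for inositol metabolism, as given above, and for cholesterol synthesis (0.11 in females and 0.01 in males, without HT vehicle female replicate 1). These differences between the sexes were not tested for lists. Ribosomal protein genes fell in 31 of 78 cases (58 over the list alone; mean -0.14, adjusted p = 3.8e-28, adjusted p = 0.2 with an estimated correlation), with Rps18 at 0.843-fold, where it fell by 0.39 on the log2 scale in females and by 0.10 in males. Oxidative phosphorylation genes had 1 fall among 80 (0 over the list alone; adjusted p = 0.0037, adjusted p = 0.64 with an estimated correlation), and the list had adjusted p = 0.61 and the opposite sign after length and GC correction. Genes that rose were 4 of 40 for ankyrins and spectrins (9 over the list alone; adjusted p = 2.2e-05, adjusted p = 0.27 with an estimated correlation), with the potassium channel gene Kcna1 at 1.26-fold, 7 of 57 for channels (9 over the list alone; adjusted p = 8.5e-05, adjusted p = 0.23 with an estimated correlation), and 5 of 54 for presynaptic release (8 over the list alone; adjusted p = 0.00018, adjusted p = 0.52 with an estimated correlation), with the complexin gene Cplx1 at 1.13-fold. They were 4 of 87 for autism risk genes, of which 1 fell (the same numbers over the list alone; adjusted p = 0.03, adjusted p = 0.52 with an estimated correlation), 1 of 20 for excitatory neurons (2 over the list alone; adjusted p = 0.0064, adjusted p = 0.52 with an estimated correlation), 0 of 61 for glutamate receptors (0 over the list alone; adjusted p = 0.036, adjusted p = 0.58 with an estimated correlation), and 1 of 13 for mitochondrially encoded mRNAs (1 over the list alone; adjusted p = 0.0093, adjusted p = 0.52 with an estimated correlation), mt-Nd6. The 847 calls became 1597 without HT vehicle female replicate 1, 427 without its replicate 3, 356 without replicate 4, 536 without HT lithium female replicate 2 and 513 without HT lithium male replicate 4. Without the 4 libraries that stood apart, 2087 genes were called, and without a filter on low values 448.

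Lithium in WT and HT shared 87 genes higher in both genotypes (6.18 expected if independent) and 36 lower in both (3.41 expected), with none opposite. No gene differed in its lithium response between genotypes or sexes by limma (0 called each, with 1139 and 2500 at an unadjusted p under 0.05, the smallest adjusted p by sex being 0.0779). The smallest p for a difference between genotypes were those of Sat1, a polyamine enzyme gene (-0.37, adjusted p = 0.23), Cops9 (-0.31, adjusted p = 0.43), and Rpl27 (-0.29), Rps18 (-0.25) and Rbm7 (-0.21), each with adjusted p = 0.49. Without HT vehicle female replicate 1, 5 genes differed between genotypes and 6 between sexes. Without HT lithium male replicate 2 the counts were 1 and 22. Without the 4 libraries that stood apart, 18 genes differed between genotypes and 299 between sexes, and a model of the compared groups alone called 87 between sexes. Quantile normalization gave 5 between sexes, and equal sums 1 in each comparison. By sex, 12, 24, 26 and 17 differed without WT lithium female replicate 5, HT vehicle female replicate 5, and WT vehicle female replicates 3 and 5.

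In HT, 753 genes passed with lithium in females and 3 in males, against 175 and 36 with a model of the compared groups alone and 2169 and 49 without the 4 libraries that stood apart. For lithium in HT, females, and lithium in HT, males, the counts were 401 and 8 after length and GC correction and 483 and 4 without a filter on low values. The female count was 341, 486 and 429 without HT lithium replicates 2, 4 and 5, and 1669, 391, 286 and 192 without HT vehicle replicates 1, 2, 3 and 4. The male count was 5 and 1 without HT lithium replicates 2 and 3, and 7, 5, 1 and 1 without HT vehicle replicates 1, 2, 3 and 4. In WT, 199 genes passed in females and 11 in males, against 41 and 39 with a model of the compared groups alone and 409 and 55 without the 4 libraries. For lithium in WT, females, and lithium in WT, males, they were 106 and 5 without a filter on low values. The female count was 100, 130 and 63 without WT lithium replicates 1, 2 and 3, and 86 and 43 without WT vehicle replicates 1 and 2. The male count was 2, 0 and 7 without WT lithium replicates 1, 4 and 5, and 7, 29, 2, 6 and 6 without WT vehicle replicates 1 to 5.

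The last comparison asks which differences from untreated WT stand in treated HT cortex. Ank2 stayed below WT vehicle, at 0.758-fold in HT fluoxetine (adjusted p = 2.3e-10) and 0.706-fold in HT lithium (adjusted p = 7.1e-14). With fluoxetine, 1531 genes were higher and 1658 lower than in WT vehicle (3189 together), with Bc1 (2.28-fold), the matricellular gene Thbs4 (2.08-fold), mt-Nd4l (1.95-fold), Hif3a, a hypoxia-inducible factor gene (1.79-fold), and Kirrel2 (1.77-fold) among the largest rises. The largest falls were those of S100a5 (0.136-fold), Shisa3 (0.279-fold), Th, the tyrosine hydroxylase (0.309-fold), Doc2g (0.33-fold), Vipr2 (0.335-fold) and Trh (0.359-fold), genes known for their expression in the olfactory bulb, whose levels rose and fell together between libraries of the same group. With lithium, 703 genes were higher and 635 lower (1338 together), with Arc at 1.99-fold, Egr2 at 1.86-fold and Tnfrsf25 at 1.64-fold. Another 6 olfactory bulb genes (Tbx21, Eomes, Cdhr1, Sp8, Pcp4l1 and Nmb) had a mean of -1.25 (SE 0.49) in this comparison. Falls included Calb2, the calretinin gene (0.446-fold), the transcription factor genes Sp9 (0.522-fold) and Dlx1 (0.535-fold), and Gng4 (0.541-fold). Whether these falls follow the olfactory bulb genes was not tested. The cortical inhibitory neuron genes Gad1, Slc32a1, Lhx6, Sst, Pvalb and Vip had a mean of 0.08 (SE 0.04) with lithium. The lithium count was 847 without HT lithium female replicate 2, 807 without WT vehicle female replicate 1 and 886 without its replicate 2.

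Across all 16919 genes, which are not independent replicates, the log2 changes of fluoxetine in WT and HT correlated with r = 0.52 (-0.28 to 0.29 in 100 simulations without effects). Those of lithium had r = 0.29, inside its simulated range of -0.34 to 0.32. The genotype change correlated with the change by fluoxetine in HT at r = -0.19, and by lithium at -0.25. Both pairs share the HT vehicle libraries, which gives a mean r of -0.48 without any effect, and both values lie inside the simulated ranges (-0.72 to -0.16 and -0.76 to -0.20). The covariance minus the mean simulated one was 0.00445 and 0.00403. With the vehicle libraries divided, r was 0.10 for each. Fluoxetine and lithium correlated at r = 0.19 in WT and 0.49 in HT, both inside the simulated ranges (0.17 to 0.68 and 0.13 to 0.67, with a mean of 0.47 each). The covariance minus the mean simulated one was -0.00479 in WT and 0.0128 in HT, and with divided vehicle libraries r was -0.15 and 0.20. The genotype changes of females and males correlated at r = -0.02 (-0.33 to 0.40 in simulation). Called genes shared by fluoxetine and lithium in HT were 124 higher and 151 lower, with 5 and 10 opposite. In WT they were 21 and 24, with 5 and 13 opposite. The 2 drugs share their vehicle libraries, so these counts have no value without an effect to be set against here. Without HT vehicle female replicate 1, the lithium change in HT females correlated with the WT fluoxetine change at r = 0.39. That in HT males did so at r = 0.02. Neither shares libraries with the WT fluoxetine change, and the HT lithium females are those with high length slopes.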

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

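The tests on transcript length and GC content, on the library property shared with HT lithium females, and on immediate early genes in HT vehicle female replicate 1 were chosen only after the result they measure was seen.

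With fluoxetine, ribosomal protein and respiratory chain mRNAs were lower and long neuronal mRNAs higher. Removing the trend with transcript length and GC content left the ribosomal mean at -0.13 (SE 0.02) from -0.26 in WT, which argues against that trend as the whole cause there. For the neuronal lists the evidence is weaker: 5 of 5 were still called upward in both genotypes with the preset correlation, but their mean went from 0.11 to 0.05 in WT and from 0.08 to 0.04 in HT (SE 0.021 each), and before the correction 3 of the 5 in WT and 4 in HT were not called with an estimated correlation. Taken by sex, which was not tested, corrected means in WT females and males were 0.08 and 0.00 (SE 0.03 each) for glutamate receptors. They were 0.15 (SE 0.05) and 0.00 (SE 0.06) for presynaptic release, and 0.11 (SE 0.04) and 0.01 (SE 0.05) for ankyrins and spectrins. In HT, without HT vehicle female replicate 1, these pairs were 0.04 and 0.06, 0.09 and 0.07, and 0.10 and 0.05. A property that varies between lithium libraries of the same group is not decided. With corrected values, gene slopes on the length slope among those libraries correlated with the WT fluoxetine change at r = 0.04. The length trend had been removed beforehand, and length slopes within those groups had SDs of 0.013 to 0.025. WT fluoxetine libraries differed from WT vehicle by 0.087 in length slope. A library property shared with the HT lithium female libraries stays open. Their lithium change minus that of males correlated with the WT fluoxetine change at r = 0.35 (0.33 with corrected values), against -0.02 for the same quantity in WT. No batch is given, so a batch may account for the ribosomal, respiratory and neuronal changes, an effect of fluoxetine may as well, and these cannot be told apart.

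HT vehicle female replicate 1 had values like those of lithium libraries. Its deviation correlated with the HT male lithium effect at r = 0.24, which a lithium-treated animal under a vehicle label would give. In the other 14 vehicle libraries that share none with that effect r was -0.24 to 0.04, and in the 5 HT vehicle males, set against the WT male effect, -0.08 to 0.17. A response confined to the early gene lists is argued against by lithium genes outside them. Their mean signed deviation was 0.154, against -0.068 to 0.017 in the other 4 libraries of the group. These genes may include others that neurons transcribe on activity, so a wider activity response was not tested. A transcript length trend is argued against by r = 0.26 with corrected values. A lithium-treated animal is a candidate explanation, the library property of the fluoxetine libraries (r = 0.31 with the WT fluoxetine change) stays open beside it, and the library was kept in its labelled group.

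In treated HT against WT vehicle libraries, S100a5, Doc2g, Th, Trh, Shisa3 and Vipr2 were lower. Within groups over 59 libraries their mean correlated with that of 6 other olfactory bulb genes (Tbx21, Eomes, Cdhr1, Sp8, Pcp4l1 and Nmb) at r = 0.97. The permutation p was 1e-05, the smallest that 100000 permutations can give. Olfactory bulb tissue in some dissections may explain this correlation. With fluoxetine, 6 cortical inhibitory neuron genes had a mean change of -0.09 (SE 0.04), where the bulb genes changed by -1.31 (SE 0.49). This argues against a fall of cortical inhibitory neuron mRNAs as large as that of the bulb genes. It does not argue against a small fall. Against their own vehicle the 6 other bulb genes had means of -0.33 (SE 0.51) and -0.76 (SE 0.49) with fluoxetine in WT and HT. Their means were -0.12 and -0.70 (SE 0.49 each) with lithium, and -0.55 (SE 0.49) for genotype. An effect of a drug or of genotype is thus neither shown nor excluded.

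Of 108 combinations of a measure and a group, 13 had a library far from the others of its group, where chance gives about 1 in 20. WT fluoxetine male replicate 1 had an estimated depth of 27 M reads (33.1 to 34.1 in the others) and an immediate early gene deviation of 0.183 (-0.313 to -0.252). Ddx3y was at 669 in HT lithium male replicate 2 (1692 to 1942) and at 1983 in WT fluoxetine male replicate 2 (1901 to 1908). HT vehicle female replicate 1 had a length slope of 0.0679 (-0.0368 to -0.0162) and a ribosomal deviation of -0.241 (0.0841 to 0.19). WT lithium female replicate 4 had an immediate early gene deviation of -0.007 (0.491 to 0.592). Oligodendrocyte and myelin genes deviated by -0.6 in HT lithium male replicate 2 (0.192 to 0.373). Choroid plexus genes deviated by 5.34 in HT fluoxetine female replicate 2 (-0.326 to 0.305) and by -0.727 in HT fluoxetine male replicate 1 (-0.219 to -0.108). Striatum genes deviated by 0.387 in WT lithium female replicate 5 (-0.26 to -0.188), by 0.472 in WT lithium male replicate 3 (-0.209 to -0.0599) and by 0.695 in WT vehicle male replicate 2 (-0.22 to -0.122).

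The response to fluoxetine differed between genotypes in 11 lists by camera, none of them by fry or with an estimated correlation (adjusted p = 0.83 for ribosomal proteins and 0.75 for the other 10). Higher in HT than in WT were the responses of oligodendrocytes and myelin (mean difference 0.16, adjusted p = 0.0024), glucocorticoid response (0.20, adjusted p = 0.0024), nuclear-encoded oxidative phosphorylation (0.03, adjusted p = 0.0051), ribosomal proteins (0.04, adjusted p = 0.011) and mitochondrially encoded mRNAs (0.14, adjusted p = 0.038). Lower were those of immediate early genes (-0.22, adjusted p = 0.00039), striatum (-0.31, adjusted p = 0.0024), fibroblasts and meninges (-0.19, adjusted p = 0.0057), autism risk genes (-0.04, adjusted p = 0.0058), inflammation and interferon response (-0.13, adjusted p = 0.015) and inhibitory neurons (-0.14, adjusted p = 0.036). Without the 4 libraries that stood apart, 4 lists were called, and oligodendrocytes and myelin, oxidative phosphorylation and ribosomal proteins changed sign (adjusted p = 0.78, 0.94 and 0.004). Without HT fluoxetine female replicate 1 the number of lists was 18, and without HT vehicle female replicate 1 it was 6.

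The response to lithium differed between genotypes in 14 lists by camera, none of them by fry or with an estimated correlation (given second). Lower in HT were the responses of ribosomal proteins (mean difference -0.14, adjusted p = 9.6e-27 and 0.23), immediate early genes (-0.30, adjusted p = 3.4e-08 and 0.24), nuclear-encoded oxidative phosphorylation (-0.07, adjusted p = 4.5e-07 and 0.5), blood cells (-0.44, adjusted p = 5.9e-05 and 0.23), inflammation and interferon response (-0.17, adjusted p = 0.00018 and 0.24), astrocytes (-0.07, adjusted p = 0.04 and 0.62) and microglia (-0.06, adjusted p = 0.04 and 0.63). Higher were those of presynaptic release (0.09, adjusted p = 2.7e-09 and 0.24), ankyrins with spectrins (0.09, adjusted p = 8.4e-07 and 0.23), glutamate receptors (0.07, adjusted p = 1.2e-06 and 0.23), potassium and calcium channels (0.06, adjusted p = 0.00012 and 0.23), autism risk genes (0.04, adjusted p = 0.00055 and 0.24), cholesterol synthesis (0.06, adjusted p = 0.0029 and 0.57) and excitatory neurons (0.10, adjusted p = 0.0043 and 0.54). Without HT vehicle female replicate 1, the lithium means in HT females, HT males, WT females and WT males were -0.29, -0.07, -0.02 and 0.01 for ribosomal proteins, -0.16, 0.02, 0.05 and 0.00 for oxidative phosphorylation, and 0.10, -0.01, 0.00 and -0.02 for autism risk genes, the HT females being those with high length slopes. For immediate early genes they were 0.35, 0.27, 0.55 and 0.54.

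For the following counts, at most 4 of 100 splits of the libraries, the real one among them, called as many genes. They are given as splits as large, real count and highest other, without adjustment over the tests. Chance is not excluded for a count where another split called as many or more: fluoxetine in HT females, lithium in HT females and males, and genotype. With fluoxetine they were 1, 2500 and 401 in WT (1, 1448 and 105 in females, 1, 896 and 335 in males) and 1, 2370 and 377 in HT (2, 1480 and 1564 in females, 1, 569 and 55 in males). With lithium they were 1, 376 and 2 in WT (1, 199 and 117 in females, 1, 11 and 1 in males) and 1, 847 and 10 in HT (4, 753 and 1096 in females, 2, 3 and 3 in males). For treated HT against WT vehicle they were 1, 3189 and 15 with fluoxetine and 1, 1338 and 106 with lithium. For genotype they were 3, 1 and 1 over both sexes and 3, 1 and 1 in males. The 1 gene is Ank2, and any split with 1 call equals this count, so the splits do not test the fall of Ank2. For the number of lists with lithium in HT, splits as large, real count and highest other were 3, 19 and 21, so that another split called more. With an estimated correlation, 0 of the 19 lists were called.

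Chance cannot be excluded for the genotype count in females (9 splits as large, real count 1, highest other 47). The 1 gene is again Ank2, whose fall in females had adjusted p = 5.1e-09 by limma and is not tested by the splits. For the counts of 0 the splits say nothing about chance, since 100 of 100 are as large whatever the data, and the highest other was 6 for genotype by sex, 570 and 4 for fluoxetine by genotype and by sex, and 1 each for lithium by genotype and by sex. Chance cannot be excluded either for these numbers of lists: genotype (79 splits, real 8, highest other 18), fluoxetine in WT (39, 12 and 20), in HT (17, 21 and 25) and by genotype (59, 11 and 20), and lithium in WT (92, 4 and 17) and by genotype (18, 14 and 19). The splits that called 47 and 570 genes, against real counts of 1 and 0, may point to a structure of the samples, as may those that called 1564 and 1096 genes in HT females. What these splits follow was not tested.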

How the results depend on the processing

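Length and GC correction, equal sums and leaving out 4 libraries were chosen after the data had been seen; numbers are called genes unless lists or r are named, and causes were not tested except where fewer libraries or more tested genes enter. Pseudocounts of 0.5 and 10 left all 325 named-gene values on their side of the threshold, and the replicate block moved no count over 1.5 times. Quantile normalization gave lithium by sex 5. No filter, which tests more genes, gave genotype 4 (females 2, males 2), fluoxetine in HT females 958, lithium in WT 212 (females 106, males 5, lists 8), lithium in HT 448 (females 483), and HT lithium against WT vehicle 816. A model of the compared groups alone gave genotype in females 0 (Ank2 fell by 0.53 there in the full model), fluoxetine in WT females 707 and males 102, in HT females 1, lithium in WT females 41 and males 39, in HT females 175 and males 36, and lithium by sex 87. Length and GC correction gave fluoxetine in WT 850 (668 shared with the 2500; females 326, males 120) and in HT 1534 (1289 shared with the 2370; males 196; fluoxetine in HT, females 891), lithium in HT females 401 and males 8, and 8 lists for lithium in WT, and turned oxidative phosphorylation with lithium in HT (adjusted p = 0.61). Of 325 named-gene values, 272 kept their side, 49 lost and 4 gained the call. Equal sums gave lithium in WT males 5, and lithium by genotype 1 and by sex 1. Without the 4 libraries there were genotype in males 2, fluoxetine in HT, females 889 and males 877, lithium in WT 582 (females 409, males 55, lists 8), in HT 2087 (818 shared with the 847; females 2169, males 49), by genotype 18 and by sex 299, and 4 lists for fluoxetine by genotype. There, oligodendrocytes with fluoxetine in HT (adjusted p = 0.97) and oligodendrocytes, oxidative phosphorylation and ribosomal proteins in fluoxetine by genotype (adjusted p = 0.78, 0.94 and 0.004) changed sign. Lists called with an estimated correlation were 0 for genotype, 6 and 4 for fluoxetine in WT and HT, 2 and 0 for lithium, and 0 and 0 for the drugs by genotype. With fry they were 0 for genotype, 13 and 17 for fluoxetine in WT and HT, 2 and 8 for lithium, and 0 and 0 by genotype. For genotype with fluoxetine in HT, r was -0.07 by rank, 0.10 over the 10108 genes with a mean of at least 10 CPM, 0.10 with divided vehicle libraries and -0.32 without the 4 libraries. For genotype with lithium in HT it was 0.05, 0.10 and -0.37 by the last 3. Lithium in WT and HT gave 0.46 over the 10108 genes, and fluoxetine with lithium -0.15 in WT and 0.20 in HT with divided vehicle libraries. Leaving out 1 library at a time gave these ranges: genotype 1 to 2 (females 1 to 1, males 1 to 2, by sex 0 to 0, lists 4 to 12); fluoxetine in WT 2047 to 2582 (females 674 to 1475, males 285 to 971, lists 11 to 16), in HT 1863 to 2716 (females 708 to 1810, males 351 to 623, lists 18 to 22), by genotype 0 to 0 (lists 6 to 18) and by sex 0 to 0. Lithium gave in WT 214 to 435 (females 43 to 252, males 0 to 29, lists 3 to 7), in HT 356 to 1597 (females 192 to 1669, males 1 to 7, lists 15 to 20), by genotype 0 to 5 (lists 12 to 19) and by sex 0 to 26. Treated HT against WT vehicle gave 2533 to 3427 with fluoxetine and 807 to 1438 with lithium. Ranges of r were -0.28 to -0.14 and -0.36 to -0.20 for genotype with fluoxetine and with lithium in HT, 0.47 to 0.56 and 0.23 to 0.34 between genotypes for fluoxetine and lithium, 0.17 to 0.23 and 0.46 to 0.55 between drugs in WT and HT, and -0.10 to 0.04 for genotype between sexes. Replicate numbers do not pair libraries across groups: 13 of 59 libraries correlated best with their own number, and the mean r was 0.0087 for the same and -0.0021 for another number. The test on counts with edgeR or DESeq2 was not run, since read counts could not be recovered.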

Other observations

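Taken by sex, which was not tested for lists, cholesterol synthesis genes had negative means with fluoxetine in both sexes and genotypes: -0.12 (SE 0.05) in HT females, -0.20 in HT males, -0.11 in WT females and -0.20 in WT males, without HT vehicle female replicate 1. With lithium in HT they had means of 0.11 in females and 0.01 in males. Genes of red blood cells had means of -0.50 and -0.50 with fluoxetine in HT females and males, -0.59 and -0.25 in WT, -0.36 and -0.45 with lithium in HT, and -0.06 and 0.10 with lithium in WT. Glucocorticoid response genes had means of 0.24 and 0.20 with fluoxetine in HT females and males (SE 0.10 each), and of 0.03 and 0.06 in WT.

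Lists that camera called in none of the 7 comparisons were ependymal cells, deep and upper cortical layers, thyroid hormone response, serotonin signalling, and perineuronal net and extracellular matrix. Their medians with fluoxetine in WT were -0.01 (adjusted p = 1) for ependymal cells, 0.04 (adjusted p = 0.51) for deep layers, 0.08 (adjusted p = 0.098) for upper layers, 0.03 (adjusted p = 0.94) for thyroid hormone response, 0.00 (adjusted p = 0.96) for serotonin signalling and 0.06 (adjusted p = 0.063) for the perineuronal net. With lithium in WT the adjusted p were 0.99, 0.28, 0.84, 0.98, 0.54 and 0.37 in the same order. With fluoxetine in HT they were 0.67, 0.78, 1, 0.38, 1 and 0.2, and with lithium in HT 0.76, 0.75, 0.7, 0.13, 0.75 and 0.88. Fibroblasts and meninges were called in fluoxetine by genotype alone.

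Median, mean and direction of the test differed in sign for lists that were not called in the comparison concerned. For genotype these were choroid plexus, ependymal cells, inositol metabolism, Wnt and GSK3 signalling, GABA receptors, autism risk genes, ribosomal proteins and the unfolded protein response. For fluoxetine they were ependymal cells, circadian clock, thyroid hormone response, serotonin signalling, CREB targets and mitochondrially encoded mRNAs in WT, microglia, endothelial cells, upper layers, Wnt and GSK3 signalling, unfolded protein response and perineuronal net in HT, and excitatory neurons, thyroid hormone response and cholesterol synthesis by genotype. For lithium they were excitatory and inhibitory neurons, oligodendrocyte precursors, ependymal cells, blood cells, circadian clock, channels and inflammation in WT, oligodendrocytes, striatum and Wnt and GSK3 signalling in HT, and striatum and Wnt and GSK3 signalling by genotype.

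HT fluoxetine female replicate 4 had Eif2s3x at 3679 and Ddx3x at 8294, X-linked genes singled out after their values were seen. The other 4 libraries of its group lay at 5127 to 5591 and 9930 to 10856, and the 5 HT fluoxetine males at 3292 to 3783 and 7446 to 8686. Its Ddx3y was at 0.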
